A study of Mus musculus with 20 samples.

How the data were processed

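RNA was measured in 12 libraries from mouse bone marrow stromal cells, in 4 groups of 3. The cells were sorted from crushed and collagenase-digested femora and tibiae, per the labels' protocols. CAR cells (CXCL12-abundant reticular cells) were gated as CD45-CD31-Lin-PDGFRα+Sca1-, and PaS cells had the same gates but were Sca1+. The genotypes were Ebf1+/+;Prx1+/cre, called wt, and Ebf1fl/fl;Prx1+/cre, called ko, both on C57BL/6. The series also lists 8 ATAC-seq samples, which have no deposited table here and were not analysed.

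Total RNA was isolated with a column kit and enriched with oligo dT beads, and libraries were made with SMART-Seq v4, per the labels' protocols. Reads were processed with bcl2fastq 2.17.1.14, TopHat2 2.0.14, Cufflinks 2.2.1 and Cuffnorm 2.2.1 on mm10, and Cuffdiff is also named, per the submitters' processing notes. The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), with 1 table of 24347 gene symbols per library, per the file headers. The order of the steps, the gene annotation and any filter are not stated. That the authors scaled the libraries to one another is read from the values: the median ratio of each library to the geometric mean of all 12 lay between 0.999 and 1.01. The labels do not say that the counting used strand, so reads of overlapping or antisense genes cannot be told apart. Near-identical genes such as Bglap and Bglap2, the hemoglobin genes, the Gbp genes and the H2 genes can share reads, and their values are uncertain for that reason.

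No read counts are given, so the depth of the libraries is unknown and no counting interval was computed. Replicates were checked to be separate libraries. Low genes whose values sit on steps of a single read gave relative depths of 0.889 to 1.12 of the mean over the libraries. These steps held for 1067 of 5707 low genes, within 0.03 of a whole number in every library. On the 281 to 451 of those genes usable in a pair of replicates, the chi-square per degree of freedom between the 2 was 3.90 to 7.95, above counting noise. The labels do not say whether replicates come from separate animals or pools, so p-values measure only the spread between the samples given.

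Gene symbols were used as the files give them. Of the 24347 symbols, 23314 matched the gene name table and 24245 matched a RefSeq symbol or synonym of assembly GRCm38.p6. No coordinates are printed.

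Values were tested as log2(FPKM + 1) for genes at 1 FPKM or more in at least 3 of the 12 libraries, which left 12938 genes. Fold changes on this scale understate the change of genes with low values. A 4-group model was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), with 8 residual and 6.95 prior degrees of freedom. The contrasts were ko minus wt in CAR cells, ko minus wt in PaS cells, the difference of these effects, and wt CAR minus wt PaS. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p given for a gene comes from this two-sided limma test. Errors beside FPKM are standard deviations of 3 libraries, and errors beside log2 fold changes are standard errors of the model. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.

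There were 28 gene lists, and the 27 with at least 5 tested members were tested against all other tested genes with limma's camera at a preset inter-gene correlation of 0.01. The list of Schwann cell markers had 4 tested members and was not tested. Adjusted p-values of lists are over the lists within each contrast. Camera was repeated with an estimated correlation, and calls that this ended are given with that value; all other list calls held with it. The lists, the tests, the rule for named genes and the alternatives were chosen before the data were examined, except where a choice is named as later.

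The genes named in each contrast were Ebf1 to Ebf4 and Prrx1, the 10 largest called increases and decreases whose libraries do not overlap (5 and 5 for the difference of effects, with no overlap rule), up to 4 members of each list with the smallest p, and Cxcl12, Kitl, Il7, Lepr, Vcam1, Adipoq, Pparg, Ly6a, Pdgfra, Ptprc and Pecam1. Predicted and small RNA genes were left out, and some genes of the rule are not described. Col1a2, Gsn, Gapdh, Ppia, Pgk1, Tpt1, Rps29, Nr1d1 and the sex-linked genes were chosen after their values were seen, apart from Xist and the Y-linked genes.

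A value of exactly 0 where another library of the group had at least 100 FPKM was treated as a failed estimate in an alternative chosen after seeing the data. The other alternatives were a pseudocount of 0.1 or 5, no filter, a filter of 5 FPKM, median-ratio scaling, quantile normalization, library weights, fitting only the groups compared, leaving out small RNA and predicted genes, the replicate number as a block, leaving out each library in turn, and fry for the lists.

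The tests were tried on simulated data of 12938 genes with 200 changed genes, 100 of them by a log2 fold change of 0.5 and 100 by 1. In the CAR comparison 24% of the smaller and 82% of the larger changes were called, with 6 false calls. In the PaS comparison these were 27% and 83%, with 7 false calls. In wt CAR against wt PaS they were 33% and 76%, with 4 false calls. For the difference of effects they were 12% and 58%, with 0 false calls. The simulated noise was independent between genes, and fewer genes were changed than the real comparisons called. The shares called and the false calls may therefore differ in the real data.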

Results

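The data describe gene expression in 2 stromal cell populations of mouse bone marrow with and without a conditional deletion of Ebf1, a transcription factor of B cell and mesenchymal development. CAR cells are the main source of Cxcl12 in the marrow, and PaS cells are PDGFRα+Sca1+ mesenchymal progenitors. Each of the groups CAR wt, CAR ko, PaS wt and PaS ko had 3 RNA libraries. Summed values ran from 491801 to 526074 FPKM per library, and 11863 to 12295 genes had at least 1 FPKM. The read depth is not given. The PaS wt library of replicate 1 stood apart in listing 24.6% of genes at 0, against 33.3% to 37.0% in the other 11 libraries.

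Ebf1, the targeted gene, was not lower in any group of libraries labelled ko. It had 48.1 ± 1.10 FPKM in CAR wt and 57.5 ± 1.99 FPKM in CAR ko libraries (n = 3 each), a log2 fold change of 0.25 (SE 0.08, adjusted p = 0.040). An exact two-sided permutation test of these 6 values gave p = 0.1, the smallest that 3 against 3 libraries allow. The adjusted p rose above the threshold without a filter, at 0.052, under quantile normalization, at 0.065, and without any single CAR library, at 0.065 to 0.13. In PaS cells Ebf1 had 55.9 ± 5.89 FPKM in wt and 62.5 ± 2.18 FPKM in ko libraries (log2 fold change 0.16, adjusted p = 0.25; exact permutation p = 0.3). FPKM of the whole gene can include exons outside a deleted part, so these values do not check the labels, and groups are named below as the labels name them.

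**Figure D1:**
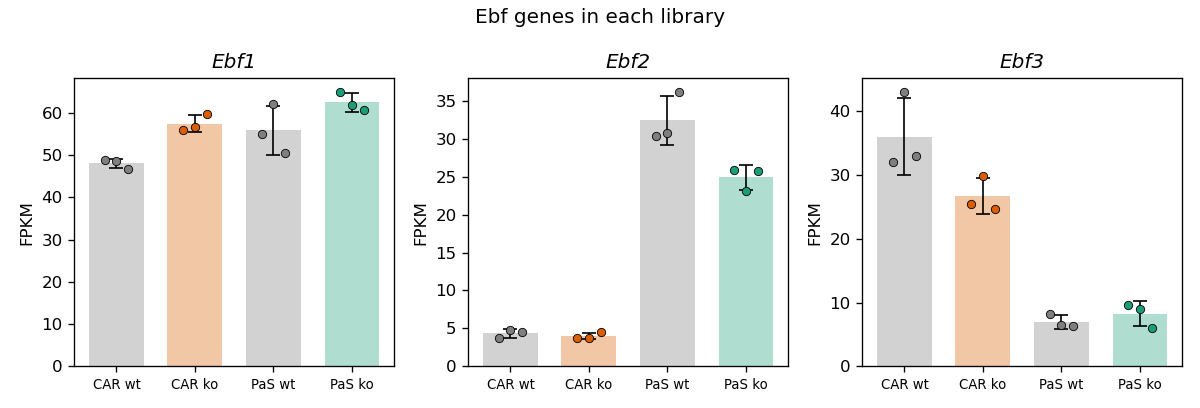
FPKM of Ebf1, Ebf2 and Ebf3 in each library (points), with the mean (bar) and standard deviation (line) of the 3 libraries of each group. Ebf1 is at 48.1 FPKM in CAR wt and 57.5 FPKM in CAR ko libraries, Ebf2 is highest in PaS and Ebf3 highest in CAR libraries.

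The first comparison asks how CAR cells differ when Ebf1 is targeted in limb mesenchyme. In libraries labelled ko, bone-forming genes were higher, cartilage collagens of type IX were lower, and transcripts of blood cells were lower. Postn, a matrix protein of periosteum and bone, rose from 165 ± 5.12 to 425 ± 2.41 FPKM (log2 fold change 1.36, SE 0.05, adjusted p = 4.9e-10). Cilp, a cartilage matrix protein, rose from 121 ± 6.87 to 348 ± 9.33 FPKM (log2 fold change 1.51, SE 0.06, adjusted p = 4.9e-10). Col9a3, a chain of type IX collagen, fell from 29.1 ± 4.33 to 6.13 ± 0.777 FPKM (log2 fold change -2.07, SE 0.14, adjusted p = 1.1e-07), and Col9a2 and Lect1, an angiogenesis inhibitor of cartilage, had log2 fold changes of -2.02 and -2.01. The mast cell and basophil proteases Prss34 and Mcpt8 rose, Prss34 from 3.87 ± 2.47 to 56.2 ± 8.01 FPKM (log2 fold change 3.65, SE 0.27, adjusted p = 3.2e-07) and Mcpt8 by a log2 fold change of 2.68.

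Among the niche genes, Cxcl12, the chemokine that retains hematopoietic stem cells, had 13251 ± 377 FPKM in CAR wt and 13299 ± 1205 FPKM in CAR ko libraries (log2 fold change 0.00, SE 0.07, adjusted p = 0.99). Under quantile normalization, which forces the most abundant genes to shared values, Cxcl12 had a log2 fold change of -0.50 (adjusted p = 0.012). Kitl, the stem cell factor, fell from 130 ± 2.51 to 106 ± 6.04 FPKM (log2 fold change -0.29, SE 0.08, adjusted p = 0.032). That call was lost without a filter, at an adjusted p of 0.063, and without any single CAR library other than ko replicate 3, at 0.062 to 0.12. Adipoq, an adipokine of CAR cells, fell from 1854 ± 69.3 to 1453 ± 10.0 FPKM (log2 fold change -0.35, SE 0.05, adjusted p = 2.2e-04). Lepr, the leptin receptor, had a log2 fold change of -0.21 (adjusted p = 0.099), and without CAR ko replicate 1 -0.30 (adjusted p = 0.0090). Il7 had a log2 fold change of 0.13 (adjusted p = 0.70), Vcam1 -0.03 (adjusted p = 0.87) and Pparg -0.04 (adjusted p = 0.88). Ebf3 had a log2 fold change of -0.41 (adjusted p = 0.11), Ebf2 -0.10 (adjusted p = 0.68), Ebf4 -0.18 (adjusted p = 0.70) and Prrx1 0.09 (adjusted p = 0.64). Ly6a, which encodes Sca1, rose from 4.66 ± 0.815 to 8.82 ± 3.01 FPKM (adjusted p = 0.0042), far below its level in PaS cells. Pdgfra had a log2 fold change of 0.16 (adjusted p = 0.15) and Pecam1 0.06 (adjusted p = 0.86).

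In all, 1585 of 12938 genes were called in CAR cells, 842 higher and 743 lower, and 237 of them by more than 2-fold (75 higher, 162 lower). The groups did not overlap for 29.9% of tested genes, where chance gives 10%. Other large increases were Cldn5, Gbp8, Gbp4, Otor, Prss35, Hhipl2 and Slurp1, with log2 fold changes of 1.55 to 1.74. Uts2 was listed at 0 in all 3 wt libraries and at 2.86 ± 1.21 FPKM in ko libraries. Other large decreases were Dbp, a transcription factor of the circadian clock, at -2.25, the eosinophil granule proteins Prg2 at -3.08 and Prg3 at -1.84, the pre-B cell gene Igll1 at -2.16, and the myeloid genes Ms4a6c at -1.85 and Ly86 at -1.83. Col1a1, the main collagen of bone, had a log2 fold change of -8.28 (adjusted p = 0.017) only because it is listed at 0 in 2 CAR ko libraries beside 4677 FPKM in the other. With these failed estimates set to missing it had a log2 fold change of -0.16 (adjusted p = 0.25).

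Of the 21 tested osteoblast lineage genes, 16 rose and 1, Col1a1, was lower (16 and 1 adjusted over the list alone). The list was called higher (adjusted p = 1.8e-12), with a median log2 fold change of 0.52 and a mean of 0.02. Col1a1 pulls this mean down, and so does its member Col1a2, which is listed at 0 in CAR ko replicate 2. Bglap, which encodes osteocalcin, rose from 4958 ± 753 to 11269 ± 2551 FPKM, Bglap2 had a log2 fold change of 1.19, and Alpl, the alkaline phosphatase of mineralisation, rose from 349 ± 28.9 to 683 ± 41.1 FPKM. Of 18 chondrocyte genes, 10 rose and 5 fell (10 and 5 adjusted over the list alone). That list was called higher (adjusted p = 0.040, or adjusted p = 0.21 with an estimated correlation), but its median was 0.36 and its mean -0.05. Prg4, the lubricin of joint surfaces, rose from 259 ± 47.3 to 691 ± 27.2 FPKM while the type IX collagens fell. Of 41 extracellular matrix genes, 18 rose and 3 fell (19 and 4 adjusted over the list alone; adjusted p = 1.2e-06, or adjusted p = 0.063 with an estimated correlation). They included Lum at 0.77, Mmp2 at 0.72, Mmp13 at 0.69 and Thbs1 at 0.91. Of 38 cell adhesion genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 2.6e-04), among them Nt5e at 0.83 and Cadm1 at 0.82. Of 17 Wnt targets, 5 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.0075), and the secreted Wnt antagonist Dkk1 rose by a log2 fold change of 1.25.

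Of 22 CAR cell markers, 1 rose and 7 fell (1 and 15 adjusted over the list alone), and the list was called lower (adjusted p = 7.0e-07, or adjusted p = 0.13 with an estimated correlation). Cbln1 fell by 1.00 on the log2 scale, the chemokine Cxcl14 by 0.47 and the angiotensinogen gene Agt by 0.32. Of 24 PaS and fibroblast markers, 9 rose and 3 fell (10 and 4 adjusted over the list alone; adjusted p = 0.019, or adjusted p = 0.16 with an estimated correlation). The chemokine scavenger receptor Ackr3 rose by 1.51, the hyaluronan synthase Has1 by 1.00 and Dcn, decorin, by 0.79. Of 20 HSC niche factors, 2 rose, including Spp1, osteopontin, from 11075 ± 580 to 18038 ± 600 FPKM, and 5 fell, including Bmp6 from 188 ± 18.0 to 137 ± 10.4 FPKM (2 and 6 adjusted over the list alone; adjusted p of the list = 0.35). Of 22 stromal transcription factors, 4 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p of the list = 0.80), with Osr2 at 0.72, Osr1 at 0.60 and Foxc1, which maintains CAR cells, at -0.35. Of 19 adipocyte genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p of the list = 0.39), and Cebpa had a log2 fold change of -0.48.

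Blood-cell transcripts were lower in ko-labelled CAR libraries although CD45+, CD31+ and Lin+ cells were gated out. The 76 genes of the blood-cell lists held 3.12% to 3.59% of all FPKM in CAR wt and 1.5% to 1.61% in CAR ko libraries. All 17 neutrophil and granulocyte precursor genes fell (17 adjusted over the list alone; adjusted p = 2.9e-30), S100a8 from 5424 ± 519 to 2357 ± 179 FPKM and Elane by 1.65 on the log2 scale. Of 15 lymphoid and pan-leukocyte genes, 14 fell (14 adjusted over the list alone; adjusted p = 1.2e-21), and Ptprc, which encodes CD45, fell from 6.46 ± 1.36 to 2.50 ± 0.600 FPKM. Of 13 erythroid genes, 9 fell (12 adjusted over the list alone; adjusted p = 1.1e-09), and Car1 fell from 190 ± 2.42 to 120 ± 8.66 FPKM. Of 16 monocyte and macrophage genes, 8 fell (8 adjusted over the list alone; adjusted p = 2.6e-06, or adjusted p = 0.059 with an estimated correlation). Of 9 megakaryocyte genes, 4 fell (8 adjusted over the list alone; adjusted p = 7.7e-06, or adjusted p = 0.20 with an estimated correlation). Beside this share, 18 of 24 cell cycle genes fell (22 adjusted over the list alone; adjusted p = 1.2e-13), Birc5 from 57.9 ± 5.27 to 36.7 ± 3.86 FPKM. Also beside it, 12 of 17 antigen presentation genes fell (14 adjusted over the list alone; adjusted p = 5.7e-11), including Cd74 at -0.71 and B2m at -0.32.

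Endothelial genes were called higher (2 of 15, or 5 adjusted over the list alone; adjusted p = 0.0058, or adjusted p = 0.11 with an estimated correlation), with Plvap at 0.81. Ribosomal protein genes were called lower (6 of 37, or 8 adjusted over the list alone; adjusted p = 1.4e-05, or adjusted p = 0.25 with an estimated correlation). Gapdh, Ppia, Pgk1, Tpt1 and Rps29 had values in all 12 libraries far below those usual for such abundant genes, with Gapdh at 1.30 to 2.08 FPKM, which limits the ribosomal and glycolysis lists. Lists not called were chemokines and cytokines (2 higher, 6 lower; 5 and 8 adjusted over the list alone; adjusted p = 0.11), hypoxia and glycolysis (3 higher, 3 adjusted over the list alone; adjusted p = 0.055) and dissociation stress (3 higher, 1 lower, the same adjusted over the list alone; adjusted p = 0.055). The interferon, TGF-beta and BMP, cholesterol, pericyte and skeletal muscle lists had adjusted p-values of 0.66, 0.19, 0.35, 0.64 and 0.45.

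**Figure D2:**
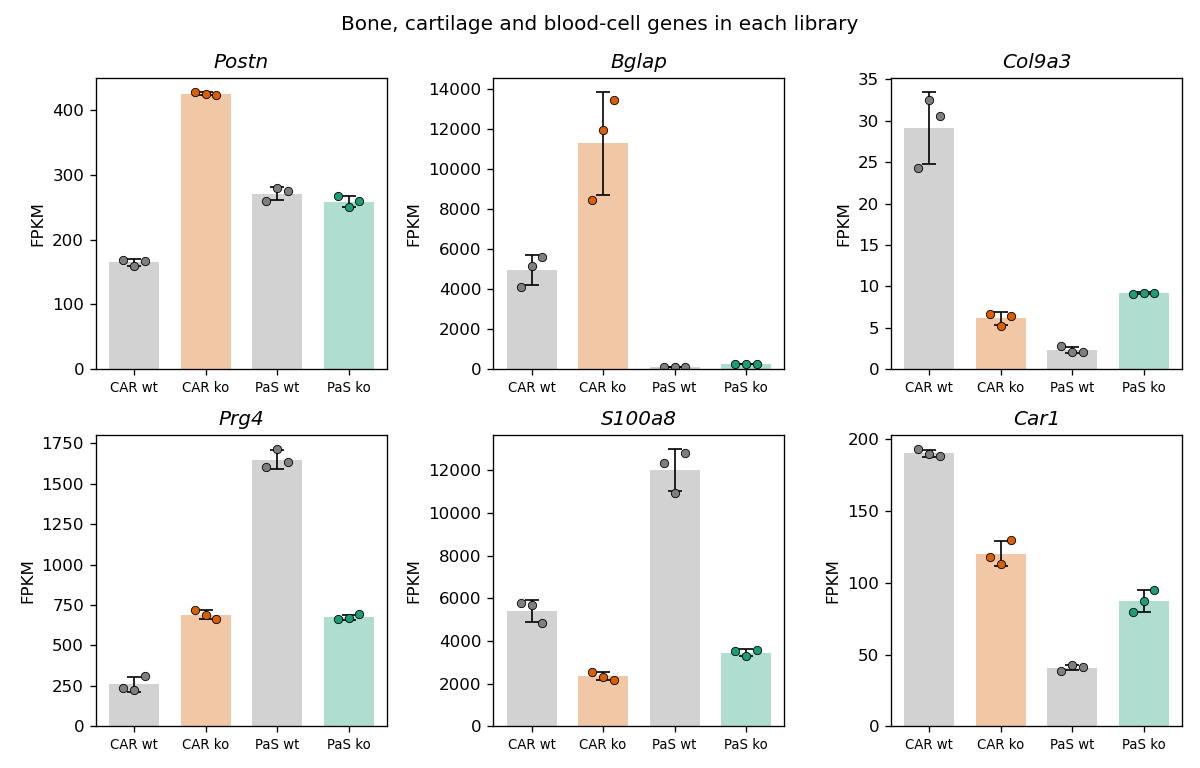
FPKM of 6 genes in each library (points), with the mean (bar) and standard deviation (line) of the 3 libraries of each group. Postn is at 165 FPKM in CAR wt and 425 FPKM in CAR ko libraries, Col9a3 and Prg4 move in opposite directions in CAR and PaS libraries, and S100a8 is lower in both ko groups.

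The same question was put to PaS cells. In libraries labelled ko, cartilage and bone genes were higher, granulocyte genes were lower, and several markers of PaS cells and genes of cholesterol synthesis were lower. Cfd, the adipokine adipsin, rose from 2.64 ± 0.351 to 32.8 ± 2.31 FPKM (log2 fold change 3.22, SE 0.20, adjusted p = 5.6e-08). Msmp, a secreted microseminoprotein, rose from 92.1 ± 13.5 to 449 ± 14 FPKM (log2 fold change 2.28, SE 0.12, adjusted p = 1.4e-08). Chil3, a chitinase-like protein of myeloid cells, fell from 209 ± 9.15 to 48.8 ± 1.68 FPKM (log2 fold change -2.07, SE 0.08, adjusted p = 5.3e-10). Pf4, a platelet chemokine, fell from 288 ± 29.2 to 28.8 ± 5.87 FPKM (log2 fold change -3.29, SE 0.60, adjusted p = 0.0023).

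In PaS cells 962 genes were called, 441 higher and 521 lower, and 217 of them by more than 2-fold (75 higher, 142 lower). Without the PaS wt library of replicate 1 this count was 748, within the 735 to 826 found without any single PaS library. The groups did not overlap for 23.4% of tested genes, against 10% by chance. Other large increases were Car4, Matn3, Timd4, Syndig1, Edn2, Lect1, Cda and Otor, with log2 fold changes of 1.76 to 2.76. Other large decreases were Prss34 at -2.62, Mcpt8 at -2.22, Ifitm6 at -2.09, Alox15 at -2.04, Ccr1 at -1.97, Cxcr2 at -1.94 and the neutrophil lipocalin Lcn2 at -1.93. Treml1, a platelet receptor, had -2.34 (adjusted p = 0.020), a call lost without a filter, at 0.11, and without replicate 1 or 3 of either PaS group, at 0.061 to 0.075. Among the fixed genes, Pdgfra, the sort marker, fell from 142 ± 6.64 to 111 ± 4.57 FPKM (adjusted p = 0.0032) and Vcam1, an adhesion molecule for blood cells, rose from 246 ± 9.12 to 303 ± 38.8 FPKM (log2 fold change 0.29, adjusted p = 0.037). This call of Vcam1 was lost without a filter, under quantile normalization, with only the PaS groups fitted, and without any single PaS wt library or PaS ko replicate 1, at an adjusted p of 0.053 to 0.16. Ly6a had a log2 fold change of -0.33 (adjusted p = 0.26), Ebf2 -0.37 (adjusted p = 0.081), Ebf3 0.19 (adjusted p = 0.57), Ebf4 0.54 (adjusted p = 0.21) and Prrx1 0.03 (adjusted p = 0.91). Cxcl12 had 4277 ± 84.8 FPKM in wt and 4388 ± 389 FPKM in ko libraries (adjusted p = 0.86), Kitl a log2 fold change of -0.01 (adjusted p = 0.98), Lepr -0.02 (adjusted p = 0.92), Adipoq 0.08 (adjusted p = 0.41), Il7 0.10 (adjusted p = 0.82), Pparg 0.18 (adjusted p = 0.41) and Ptprc -0.41 (adjusted p = 0.20).

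Of 18 chondrocyte genes, 13 rose and 1 fell (15 and 1 adjusted over the list alone; adjusted p = 7.2e-17). Chad, a cartilage leucine-rich protein, rose from 407 ± 25.0 to 800 ± 31.9 FPKM, Fmod, fibromodulin, rose by 0.86 on the log2 scale and the cartilage matrilin Matn3 by 2.02, while Prg4 fell from 1650 ± 57.3 to 675 ± 14.5 FPKM. Of 21 osteoblast genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 4.8e-07). Alpl rose from 92.1 ± 3.09 to 141 ± 6.03 FPKM and Bglap2 by 1.15, and Smpd3, a sphingomyelinase of skeletal development, fell by 1.27. Of 17 Wnt targets, 6 rose and 1 fell (6 and 2 adjusted over the list alone; adjusted p = 2.6e-04), with Wisp1 at 1.14, the antagonists Dkk3 at 0.79 and Wif1 at 0.69, and Lgr5 at 1.02. Of 24 PaS and fibroblast markers, 1 rose and 9 fell (1 and 11 adjusted over the list alone; adjusted p = 4.1e-08), including Has1 at -0.86, Efemp1 at -0.76 and Anxa3 at -0.65. Gsn enters this list as its largest rise, at 4.04, because it is listed at 0 in PaS wt replicate 2. Its other wt libraries had 14224 and 14502 FPKM, and its ko libraries 9491 to 10142 FPKM. Of 19 cholesterol synthesis genes, 8 fell and 0 rose (10 adjusted over the list alone; adjusted p = 4.8e-07), with the squalene epoxidase Sqle at -0.67. Of 12 pericyte and smooth muscle genes, 3 rose (4 adjusted over the list alone; adjusted p = 0.020, or adjusted p = 0.16 with an estimated correlation), with Tagln at 0.96, Acta2 at 0.94 and Rgs5 at 1.13.

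Of 20 HSC niche factors, 5 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p of the list = 0.31, with a median of -0.01 and a mean of 0.04). Spp1 rose from 1458 ± 102 to 2704 ± 160 FPKM and the growth factor Ptn by 0.64, and the matricellular gene Nov fell from 462 ± 5.62 to 276 ± 22.6 FPKM. Of 22 CAR cell markers, 4 rose and 3 fell (5 and 3 adjusted over the list alone; adjusted p of the list = 0.11), with Trf at 0.56 and Cxcl14 at -0.55. Of 19 adipocyte genes, 3 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p of the list = 0.21), including Fabp4 at 0.45 and Scd1 at -0.75. Of 41 extracellular matrix genes, 13 rose and 10 fell (15 and 13 adjusted over the list alone; adjusted p of the list = 0.83, with a median of -0.05 and a mean of 0.01). Mmp3 had a log2 fold change of 1.38 and Nid1 -0.76.

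Granulocyte transcripts were lower in ko-labelled PaS libraries and 7 of 13 erythroid genes were higher. The hemoglobin gene Hbb-b1 was nearly level, at 2032 ± 387 FPKM in PaS wt and 2067 ± 40.3 FPKM in PaS ko libraries. The blood-cell lists held 5.84% to 6.15% of FPKM in PaS wt and 2.60% to 2.70% in PaS ko libraries. Of 17 neutrophil and granulocyte precursor genes, 16 fell (16 adjusted over the list alone; adjusted p = 8.9e-38), S100a8 from 12011 ± 975 to 3453 ± 149 FPKM and Ngp by 1.76 on the log2 scale. Of 9 megakaryocyte genes, 6 fell (8 adjusted over the list alone; adjusted p = 8.9e-08, or adjusted p = 0.16 with an estimated correlation). Of 13 erythroid genes, 7 rose (7 adjusted over the list alone; adjusted p = 2.9e-07), Car1 from 40.9 ± 1.97 to 87.5 ± 7.63 FPKM. Of 16 monocyte and macrophage genes, 7 rose and 4 fell (9 and 4 adjusted over the list alone; adjusted p of the list = 0.086). The complement genes C1qa and C1qc of macrophages rose by 1.25 and 1.45, while Lyz2 and Cd14 fell by 1.24 and 1.10. Of 15 lymphoid and pan-leukocyte genes, 1 rose and 4 fell (5 and 7 adjusted over the list alone; adjusted p of the list = 0.12). Beside these shares, 9 of 23 chemokine and cytokine genes fell and 1 rose (10 and 3 adjusted over the list alone; adjusted p = 1.5e-04), with Il1b at -1.45 and Ccl3 at -1.38. Also beside them, 6 of 24 cell cycle genes rose (8 adjusted over the list alone; adjusted p = 6.7e-06), with Birc5 and Mki67 both at 0.60. Of 26 dissociation stress genes, 6 fell (10 adjusted over the list alone; adjusted p = 7.0e-04, or adjusted p = 0.25 with an estimated correlation), with the immediate early gene Egr1 at -0.27. The call of Egr1 was lost under quantile normalization (-0.14, adjusted p = 0.33) and without PaS ko replicate 3 (-0.23), at an adjusted p just above 0.05. The adhesion, interferon, antigen presentation, TGF-beta and BMP, hypoxia, ribosomal, endothelial, stromal transcription factor and skeletal muscle lists were not called, with adjusted p-values of 0.94, 0.50, 0.94, 0.19, 0.19, 0.15, 0.12, 0.30 and 0.74. Of 4 Schwann cell genes, too few to test as a list, Mbp fell by 0.75 on the log2 scale (adjusted p = 0.044). This call of Mbp was lost with a pseudocount of 0.1, without a filter, with library weights, with only the PaS groups fitted, with the replicate number as a block, and without any single PaS library other than ko replicate 3, at an adjusted p of 0.0503 to 0.19.

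**Figure D3:**
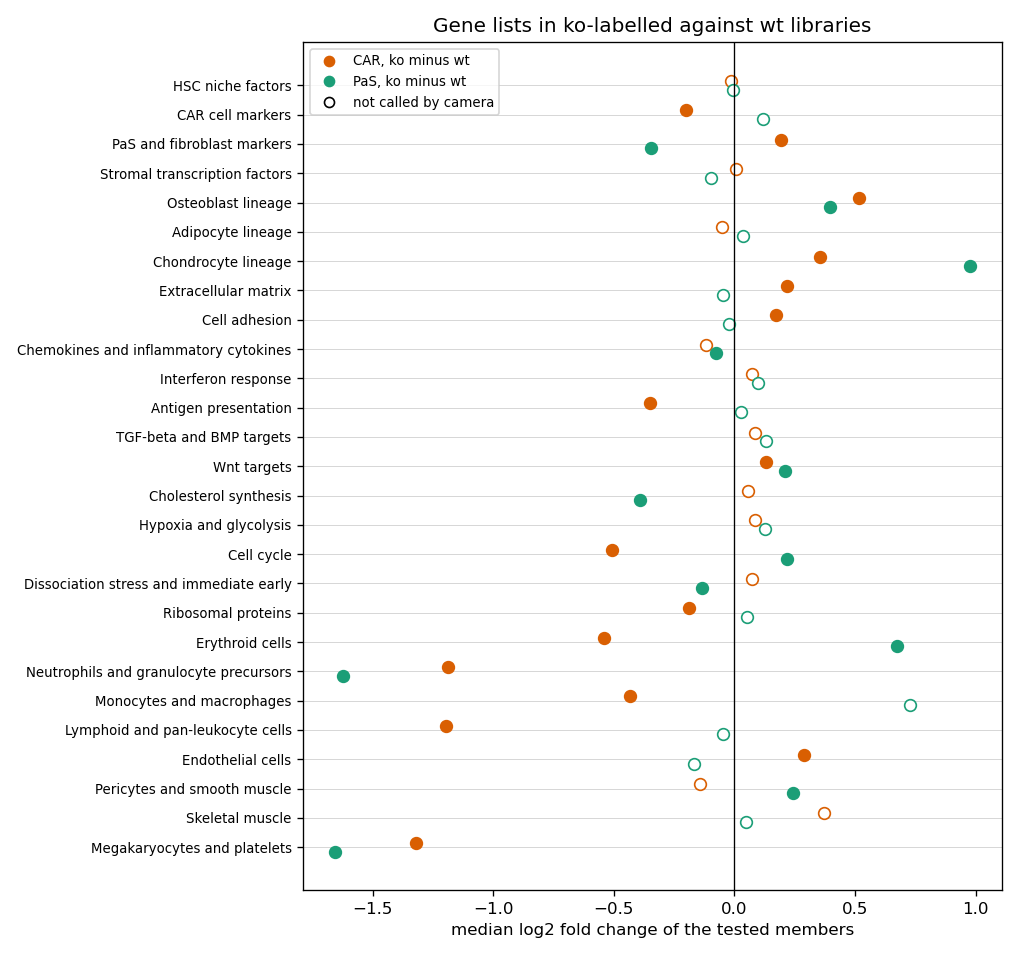
Median log2 fold change, ko minus wt, of the tested members of 27 gene lists in CAR cells (orange) and PaS cells (green), with filled points for lists called by camera at its preset correlation. Osteoblast and chondrocyte lists lie above 0 in both cell types, granulocyte genes lie below 0 in both, and erythroid and cell cycle genes lie on opposite sides.

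The difference of the effects was tested directly, as the CAR effect minus the PaS effect. The genotype effect went in opposite directions for several genes. Prg4 rose in CAR and fell in PaS cells (difference 2.71, SE 0.13, adjusted p = 8.9e-09), and so did Pcsk6, a proprotein convertase, from 19.4 ± 1.21 to 39.6 ± 0.388 FPKM in CAR and from 135 ± 2.31 to 54.2 ± 4.38 FPKM in PaS cells (difference 2.30, SE 0.10, adjusted p = 8.0e-09). Col9a3 fell in CAR and rose in PaS cells, where it went from 2.34 ± 0.374 to 9.20 ± 0.0924 FPKM (difference -3.69, SE 0.19, adjusted p = 1.6e-08), as did Lect1 (difference -3.86, SE 0.25, adjusted p = 2.1e-07) and Col9a2 (-3.47). The proteases Prss34 and Mcpt8 had differences of 6.28 and 4.90, and Fcer1a, a chain of the IgE receptor of mast cells and basophils, had 2.06 (adjusted p = 0.021). Cfd and Car4 had differences of -3.45 and -2.78. The call of Fcer1a was lost without a filter, at 0.087, and without CAR wt replicate 3, CAR ko replicate 1 or 3, PaS wt replicate 2 or PaS ko replicate 3, at 0.0505 to 0.056.

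In all 851 genes had a called difference, 429 positive and 422 negative, 281 of them by more than 2-fold (110 positive, 171 negative). Postn, which had a log2 fold change of -0.07 in PaS cells (adjusted p = 0.54), had a difference of 1.43 (adjusted p = 1.6e-08). Ebf1 had a difference of 0.09 (adjusted p = 0.71), Ebf2 0.27 (adjusted p = 0.40), Ebf4 -0.71 (adjusted p = 0.23) and Prrx1 0.06 (adjusted p = 0.86). Ebf3 had a difference of -0.60 (adjusted p = 0.14), and of -0.79 without PaS ko replicate 3 (adjusted p = 0.032). Of the niche genes, Adipoq had a difference of -0.44 (adjusted p = 0.0015), while Kitl had -0.28 (adjusted p = 0.19), Cxcl12 -0.03 (adjusted p = 0.90), Vcam1 -0.32 (adjusted p = 0.12) and Lepr -0.19 (adjusted p = 0.37). Under quantile normalization Cxcl12 had a difference of -0.67 (adjusted p = 0.026). Of 24 PaS and fibroblast markers, 9 had a positive and 0 a negative difference (12 and 0 adjusted over the list alone; adjusted p = 5.4e-10), and of 19 cholesterol genes, 6 had a positive one (8 adjusted over the list alone; adjusted p = 8.2e-06). Of 18 chondrocyte genes, 3 had a positive and 7 a negative difference (3 and 11 adjusted over the list alone; adjusted p = 3.6e-05). Of 24 cell cycle genes, 15 had a negative one (19 adjusted over the list alone; adjusted p = 2.8e-18). The osteoblast list was not called (5 positive and 0 negative, 5 and 1 adjusted over the list alone; adjusted p = 0.078, median 0.04 and mean -0.33). Its 1 negative member over the list alone is Col1a1, at -8.44 from the failed estimates (adjusted p = 0.11 over all genes). This pulls the mean down, and so does the value of 0 of Col1a2 in CAR ko replicate 2. With failed estimates set to missing Col1a1 had a difference of -0.32 (adjusted p = 0.074). The HSC niche, stromal transcription factor, adipocyte, interferon, TGF-beta and BMP, Wnt, hypoxia, skeletal muscle and megakaryocyte lists were not called, with adjusted p-values of 0.078, 0.40, 0.10, 0.82, 0.97, 0.28, 0.39, 0.78 and 0.55. For the TGF-beta and BMP list the median was 0.07 and the mean -0.01.

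The comparisons in CAR and PaS cells share no libraries, and their log2 fold changes had a Pearson correlation of 0.22 (jackknife SD 0.040) and a Spearman correlation of 0.12 across 12938 genes, which are not independent replicates. Both comparisons called 140 genes higher, where independent lists would share 28.7, and 176 genes lower, where they would share 29.9. There were 49 genes higher in CAR and lower in PaS (33.9 for independent lists) and 50 genes lower in CAR and higher in PaS (25.3). Whether the CAR and PaS cells of a genotype came from the same animals is not known here. Shared animals could raise the correlation and the overlaps, which was not tested.

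The last comparison describes the sorted populations in wt libraries. CAR cells carried bone and niche transcripts at high levels, and PaS cells carried fibroblast and Sca1 transcripts. Ly6a had 4.66 ± 0.815 FPKM in CAR and 1963 ± 218 FPKM in PaS libraries (log2 fold change -8.44, SE 0.16, adjusted p = 1.4e-15), in the direction of the Sca1 gate. Bglap had 4958 ± 753 FPKM in CAR and 121 ± 7.21 FPKM in PaS libraries (log2 fold change 5.33, SE 0.13, adjusted p = 4.1e-14). Cxcl12 was higher in CAR cells by 1.63, Kitl by 1.93, Adipoq by 1.99, Lepr by 1.48, Il7 by 1.46, Vcam1 by 1.26 and Pparg by 0.75 on the log2 scale. Ebf3 was higher in CAR cells (log2 fold change 2.2, adjusted p = 1.4e-08), Ebf2 was lower (-2.64, adjusted p = 3.9e-11), and Ebf1 had a log2 fold change of -0.21 (adjusted p = 0.037). That call of Ebf1 was lost under quantile normalization, with library weights, with only the wt groups fitted, and without any CAR wt library or PaS wt replicate 1 or 2, at an adjusted p of 0.059 to 0.18. Ebf4 had a log2 fold change of 0.15 (adjusted p = 0.62). Pdgfra, Prrx1, Ptprc and Pecam1 were lower in CAR cells, with log2 fold changes of -1.29, -0.67, -0.78 and -1.33.

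Here 5590 genes were called, 2647 higher and 2943 lower in CAR cells, 1714 of them by more than 2-fold (683 higher, 1031 lower), and the groups did not overlap for 51.2% of genes, against 10% by chance. Under quantile normalization more genes were higher than lower in CAR cells, 3144 against 2600. Other large increases in CAR cells were Col11a2, Car3, Bglap2, Prss35, Col2a1, Ifitm5, Dmp1, Entpd3 and Col11a1, with log2 fold changes of 3.62 to 5.16. Other large decreases were Ly6c1, Clec3b, Dpt, Mfap5, Pi16, Pcolce2, Inmt, Scg3 and Cyp2f2, with log2 fold changes of -7.71 to -6.11. All 22 CAR cell markers were higher (22 adjusted over the list alone; adjusted p = 1.2e-23), and 23 of 24 PaS and fibroblast markers were lower (23 adjusted over the list alone; adjusted p = 1.8e-26). Of 20 HSC niche factors, 13 were higher and 3 lower (13 and 3 adjusted over the list alone; adjusted p = 2.2e-05), and Nov was lower by a log2 fold change of -5.74. Of 21 osteoblast genes, 15 were higher and 2 lower (15 and 2 adjusted over the list alone; adjusted p = 6.4e-10). Of 24 cell cycle genes, 23 were higher (23 adjusted over the list alone; adjusted p = 2.9e-09). Of 19 cholesterol genes, 17 were lower (17 adjusted over the list alone; adjusted p = 5.2e-06), and of 15 endothelial genes, 14 (14 adjusted over the list alone; adjusted p = 6.3e-07). Of 16 monocyte and macrophage genes, 13 were lower (14 adjusted over the list alone; adjusted p = 1.0e-07), with C1qa at -4.31.

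The remaining called lists of this comparison all lost their call with an estimated correlation. Chondrocyte genes (10 higher, 6 lower), antigen presentation (12 and 4), interferon (13 and 3), TGF-beta and BMP targets (9 and 3), ribosomal proteins (19 and 0) and erythroid genes (8 and 0) were called higher in CAR cells, with adjusted p-values of 0.030, 5.2e-04, 0.015, 0.023, 8.3e-05 and 0.0015. These became adjusted p = 0.18, 0.14, 0.092, 0.089, 0.29 and 0.092 with an estimated correlation. Extracellular matrix genes (12 higher, 25 lower), stromal transcription factors (6 and 13), chemokines (5 and 13) and granulocyte genes (5 and 12) were called lower, with adjusted p-values of 7.9e-05, 0.041, 0.017 and 0.015. These became adjusted p = 0.093, 0.093, 0.093 and 0.23 with an estimated correlation. Adjusted over the list alone, these counts were the same except for 23 ribosomal genes higher and 14 chemokine genes lower. The adipocyte, adhesion, Wnt, hypoxia, dissociation stress, lymphoid, pericyte, skeletal muscle and megakaryocyte lists were not called, with adjusted p-values of 0.88, 0.18, 0.29, 0.053, 0.17, 0.18, 0.36, 0.91 and 0.67. For skeletal muscle the test's direction was up, with a median of -0.01 and a mean of -0.10.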

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

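All tests of explanations in this part were chosen after the result was seen, except the correlation of cell cycle with erythroid transcripts and the counts of other splits of the libraries. The genes and lists below stand out because the ko minus wt effect in CAR cells differs from that in PaS cells by limma's test of the difference, or by camera's for the lists. Of 132 genes taken from the report, 71 had such a difference, beside 851 of all 12938 tested genes, and of 27 lists, 17. Many of the 132 were named for the size or p-value of their changes, so their share is no result about genes at large. Ddx3x, weighed below with the sex-linked genes, is not among the 132 and also had a called difference (0.33, adjusted p = 0.035).

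In the difference, given as CAR effect minus PaS effect, cartilage and matrix genes stood on both sides. Cilp had 1.24, Postn 1.43, Prg4 2.71, Thbs1 0.96, Mmp2 0.69, Dcn 0.54, Nid1 0.46, Mfap5 0.71, Efemp1 1.25, Has1 1.85, Nov 1.05 and Smpd3 1.85. Col2a1 had -1.62, Col9a2 -3.47, Col9a3 -3.69, Lect1 -3.86, Matn3 -2.34 and Chad -0.64. Stromal, signalling and enzyme genes with a positive difference were Ackr3 at 1.89, Alpl at 0.36, Osr2 at 0.95, Pcsk6 at 2.30, Pdgfra at 0.52, Ly6a at 1.10, Ly6c1 at 1.04, Scg3 at 1.11, Hhipl2 at 1.64, Cldn5 at 1.39, Gbp4 at 1.23, Sqle at 0.67 and Scd1 at 0.79. Those with a negative one were Adipoq at -0.44, Agt at -0.41, Bmp6 at -0.45, Dkk3 at -0.44, Lgr5 at -0.85, Ptn at -0.95, Trf at -0.33, Cfd at -3.45, Car4 at -2.78, Cda at -1.58, Edn2 at -1.90, Msmp at -1.53, Syndig1 at -1.58, Timd4 at -1.86 and Cyp2f2 at -1.15. Blood and immune genes with a positive difference were Alox15 at 1.63, Ccl3 at 0.91, Ccr1 at 1.19, Chil3 at 1.02, Cxcr2 at 1.30, Fcer1a at 2.06, Ifitm6 at 1.13, Il1b at 0.63, Lcn2 at 0.99, Mcpt8 at 4.90, Ngp at 0.77, Prss34 at 6.28 and S100a8 at 0.60. Those with a negative one were B2m at -0.43, C1qa at -1.01, C1qc at -1.63, Car1 at -1.74, Cd74 at -0.84, Elane at -0.68, Igll1 at -2.59, Ly86 at -2.13, Ms4a6c at -1.06 and Prg2 at -2.10. The cell cycle genes Birc5 and Mki67 had -1.25 and -1.20.

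The call of a difference was lost without some single libraries for 14 of these genes. For Trf this held for any library but CAR ko replicate 1 and PaS ko replicate 3, at adjusted p up to 0.12. For Ccl3 it held for any library but PaS wt replicate 3 and PaS ko replicate 2, at up to 0.11. For Alpl, Ifitm6, Il1b and Sqle it held for 9 of the 12 libraries (all but CAR wt replicate 2 and 2 others), at up to 0.093, 0.072, 0.081 and 0.075. For Lgr5 it held for all but CAR wt replicate 3, CAR ko replicate 1, PaS wt replicate 2 and PaS ko replicate 2, at up to 0.066. For Ms4a6c it held for all but CAR ko replicate 1, PaS wt replicates 2 and 3 and PaS ko replicate 1, at up to 0.096. Cxcr2 lost it without replicates 1 or 3 of either CAR group or replicate 2 of either PaS group, at up to 0.082. Gbp4 lost it without CAR wt replicate 1, CAR ko replicate 2, PaS wt replicate 1 or 3 or PaS ko replicate 3, at up to 0.060. Fcer1a lost it without CAR wt replicate 3, CAR ko replicate 1 or 3, PaS wt replicate 2 or PaS ko replicate 3, at up to 0.056. Bmp6 lost it without CAR wt replicate 2, CAR ko replicate 3, PaS wt replicate 2 or PaS ko replicate 1, at up to 0.067. Hhipl2 lost it without replicate 2 of either ko group, at up to 0.054, and C1qa without PaS ko replicate 1, at 0.051. A pseudocount of 0.1 ended the calls of C1qa, Cda, Cxcr2, Cyp2f2, Gbp4 and Hhipl2 (adjusted p = 0.20, 0.15, 0.074, 0.17, 0.24 and 0.12) and of Lgr5, Ms4a6c, Scg3, Syndig1, Timd4 and Trf (0.066, 0.055, 0.39, 0.24, 0.15 and 0.052). A pseudocount of 5 ended those of Ccl3, Cldn5 and Trf (0.065, 0.19 and 0.0501). No filter ended those of Alpl, Bmp6, C1qa, Ccl3, Cxcr2, Fcer1a, Gbp4 and Hhipl2 (0.078, 0.058, 0.061, 0.13, 0.11, 0.087, 0.057 and 0.073) and of Ifitm6, Il1b, Ly6a, Mfap5, Ms4a6c, S100a8, Sqle and Trf (0.12, 0.085, 0.051, 0.059, 0.12, 0.059, 0.057 and 0.13). Quantile normalization ended those of Bmp6, Dcn, S100a8 and Trf (0.054, 0.69, 0.070 and 0.086), and the replicate number as a block those of Cxcr2, Ms4a6c and Trf (0.053, 0.061 and 0.057).

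The medians of the called lists were, in the same direction, -0.40 for antigen presentation (0 genes called positive and 5 negative, 0 and 7 adjusted over the list alone; adjusted p = 2.1e-08), 0.17 for cell adhesion (4 and 0, the same over the list alone; 0.0031), -0.68 for cell cycle (2.8e-18) and 0.42 for cholesterol synthesis (8.2e-06). They were -0.62 for chondrocyte (3.6e-05), 0.54 for endothelial (2 and 0, 6 and 1 over the list alone; 1.7e-04), -1.27 for erythroid (0 and 10, 0 and 12; 1.6e-15), -0.92 for lymphoid (0 and 9, 0 and 12; 1.3e-14), -0.90 for monocyte and macrophage (0 and 8, 1 and 10; 2.1e-08) and 0.42 for PaS and fibroblast markers (5.4e-10). A further 7 lists lost their call with an estimated correlation, given last. These were CAR cell markers at -0.28 (0 and 6, 0 and 11; 5.4e-08, then 0.11), chemokines at 0.15 (6 and 2, 8 and 3; 0.036, then 0.14), dissociation stress at 0.24 (3 and 0, 12 and 0; 5.3e-05, then 0.14) and extracellular matrix at 0.20 (13 and 1, 15 and 2; 2.5e-05, then 0.10). The others were granulocyte genes at 0.53 (8 and 4, 10 and 5; 0.0044, then 0.19), pericyte genes at -0.44 (0 and 1, the same over the list alone; 0.015, then 0.13) and ribosomal proteins at -0.23 (0 and 1, the same over the list alone; 3.3e-06, then 0.23).

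The first pattern weighed is the loss of blood-cell transcripts in ko-labelled libraries, which CD45-CD31-Lin- gates would remove. In CAR cells 17 of 17 granulocyte, 12 of 13 erythroid and 15 of 15 lymphoid genes were lower, called or not, and in PaS cells 17 of 17, 0 of 13 and 8 of 15. Less of a single blood mixture is argued against as the whole cause in PaS cells, where the erythroid mean rose. The authors' scaling by 1 factor per library is argued against in CAR cells. Less of a single blood mixture stays undecided in CAR cells, since stromal cells may express some of the listed genes, which was not tested. It would not by itself raise the mast cell and basophil genes Prss34 (3.87 to 56.2 FPKM) and Mcpt8 (4.53 to 34.5 FPKM), which are outside these lists. Those genes were named for the size of their rise, so they do not settle it for the lists. Granulocyte and erythroid genes at 10 FPKM or more in wt did not move by the same amount. Their mean log2 fold changes were -1.19 and -0.50 in CAR cells (16 and 13 genes; difference -0.689, SE over libraries 0.22) and -1.35 and 0.44 in PaS cells (16 and 8 genes; difference -1.79, SE over libraries 0.085), and in each cell type the granulocyte mean relative to the erythroid one was lower in all 3 ko-labelled libraries than in any wt library. Another make-up of carried-over blood cells and an effect of the genotype both stay open and were not tested, and whether dividing blood precursors carry the cell cycle genes is undecided, since over the 12 libraries the deviations of cell cycle and erythroid means correlated at 0.0886 (permutation p = 0.875).

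The second pattern is the clock genes Dbp (-2.25 in CAR and -1.77 in PaS cells) and Nr1d1 (-1.47, adjusted p = 1.5e-05, and -1.51, adjusted p = 1.2e-05), which were lower in all 3 ko-labelled libraries of each cell type than in any wt library. Mice taken at another time of day could show lower clock outputs and higher activators, and this pattern was tested. The pattern depends on which times are compared, so its absence would not exclude another time of day. Without Dbp and Nr1d1, which prompted the test, the median of 9 clock outputs lay at percentiles 2.99 and 1.05 of 10000 random lists of like expression in CAR and PaS cells, and that of 5 activators and antiphase genes at 84.1 and 46.8. Of these 9 outputs 2 were called lower in PaS cells, and in CAR cells 1, Usp2, was called, and it was higher (0.47, adjusted p = 0.037). The median of the outputs was low against these random lists, which take no account of correlation between genes. The activators did not rise as a list, so another time of day and the genotype itself cannot be told apart. The labels give no time of death.

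The third pattern is sex-linked genes. The median log2 fold change of 4 Y-linked genes was -0.529 in CAR and -0.83 in PaS cells, with Eif2s3y at -0.80 and -0.88 and Ddx3y at -0.46 and -0.84 (all called), Uty at -0.60 and -0.82 (adjusted p = 0.14 and 0.057) and Kdm5d at 0.06 and -0.37 (adjusted p = 0.89 and 0.32). Xist had 0.70 in CAR (adjusted p = 0.013) and 0.46 in PaS cells (adjusted p = 0.13), and was higher in all 3 ko-labelled than in all 3 wt libraries of each. A smaller share of male cells in the ko-labelled pools would also raise X-linked genes that escape inactivation, and the median of 4 of them was 0.19 in CAR cells (Ddx3x called, at 0.28, adjusted p = 0.0074) and 0.0113 in PaS cells (Ddx3x -0.05, and the lowest adjusted p 0.18, of Kdm6a at 0.28). All 12 libraries held Xist, at 3.46 to 7.58 FPKM. They also held the Y-linked Ddx3y (5.08 to 16.6 FPKM) and Eif2s3y (7.69 to 22.2 FPKM), so transcripts of both sexes were in every library. The genes that escape inactivation decide neither way on a shift of that mixture. A smaller share of male cells, for which the labels give no sex, and an effect of the genotype cannot be told apart. Any shift of that share would be confounded with the genotype in the ko minus wt comparisons, and its reach to other genes was not tested.

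Other splits of the same libraries were counted for each comparison. With 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real CAR split called 1585 genes and the highest other 2, the real PaS split 962 against 0, and the real split of the wt libraries 5590 against 0, so 1 of 10 splits was as high in each. For the difference of effects, 1 of 100 splits drawn from 200 called as many genes as the real 851, the highest other drawn calling 245. If the libraries are separate units, their chance assignment to the genotypes in both cell types is argued against at that share. The labels do not say whether replicates are separate animals or pools, so chance differences between animals or pools are not excluded. The other splits drawn break up the genotype effect in at least 1 cell type, so they cannot show that the effects differ. The split that keeps the CAR groups and swaps the PaS labels was not among those drawn.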

How the results depend on the processing

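The alternative that sets failed estimates to missing was chosen after seeing the data; the others were fixed before. The numbers of called genes stayed within 1.5 times those reported. Without 1 library at a time they were 1128 to 1262 in CAR cells, 735 to 826 in PaS cells, 644 to 760 for the difference and 5011 to 5124 in wt CAR against wt PaS cells. Under the other alternatives they were 1297 to 1915, 852 to 1052, 614 to 980 and 4506 to 5744. Which direction held more genes turned in wt CAR against wt PaS cells under quantile normalization (3144 higher and 2600 lower), in PaS cells without PaS wt replicate 3 (417 and 409), and for the difference, near equal as reported, under several alternatives (for example 375 positive and 392 negative with a pseudocount of 0.1). With failed estimates set to missing they were 1592, 975, 874 and 5603. With the replicate number as a block they were 1585, 961, 839 and 5568. Of 18 pairs of libraries with the same number, 3 had deviations from their group means correlated above 0.1 (-0.04 to 0.18). Pairs with different numbers reached 0.0926 at most, and 7 of 12 libraries correlated best with a library of their own number. These values do not rule out some pairing by number. The main model, fixed before the data were examined, did not pair libraries.

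The rise of Ebf1 in CAR cells was no longer called without a filter (0.25, adjusted p = 0.052), where more genes are tested, or under quantile normalization (0.24, adjusted p = 0.065; the cause was not tested), and without 1 CAR library it was 0.23 to 0.27. Cxcl12 in CAR cells turned to -0.50 (adjusted p = 0.012) under quantile normalization, which replaces the highest values of each library by a shared mean. Leaving out Ebf1 in the CAR and PaS comparisons, of 228 called results of named genes, 197 were called under every alternative that could test them. Over the settings of these and the uncalled named results, 4771 kept direction and call, 175 lost the call, 9 gained it and 1 reversed. Calls gained were those of Ebf2 in PaS cells at a pseudocount of 5 (-0.32) or with only the PaS groups fitted (-0.37), Ebf3 in CAR cells and Ly6a in PaS cells with only the groups compared (-0.41 and -0.33), Lepr in CAR cells with library weights (-0.23) or without CAR ko replicate 1 (-0.30), the differences of Cxcl12 and Ebf3 given in the report, and that of Col1a1 without CAR ko replicate 1 (-12.51), which leaves only its failed estimates in that group. For lists, 589 tests kept call and direction, 30 lost the call and 29 gained it, and 0 reversed. An estimated correlation accounted for 28 of the lost calls, and fry for 2 lost and 23 gained. The correlation of the CAR and PaS effects was 0.19 to 0.24. Read depth is not given, so what depth limits could not be measured.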

Other observations

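Some abundant genes are listed at 0 in single libraries, seen only after the values were read. Col1a1 is at 0 in CAR ko replicates 2 and 3 and Col1a2 in CAR ko replicate 2, where another library of the group has 4677 and 5333 FPKM, and Gsn is at 0 in PaS wt replicate 2, beside 14502 FPKM. The value of Gsn enters the PaS and fibroblast marker list in every contrast that uses PaS wt libraries.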
